A study of Mus musculus with 6 samples.

How the data were processed

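Poly(A) selection or ribosomal depletion is not given in the sources used here. Per the labels' protocols, total RNA was extracted from harvested cells with a Qiagen kit, 1 μg went into each library, and strand-specific libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name FastQC 0.11.2 and 0.11.5 and StringTie 1.3.1c, without their role. The aligner, the genome build and the annotation are not given in the sources used here.

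The deposited table held, for 24559 genes, an Ensembl gene identifier, a symbol, and 1 log2 expression value for each of the 6 libraries, as the authors computed it. The deposited log2 values were log2 of a read count divided by a library factor, plus 1. This was worked out from the values, which returned whole reads for 100% of genes in each library within a tolerance of 0.01 read (largest gap 0.00119). The recovered factors, 0.899 to 1.13, equalled median-of-ratios factors computed from the recovered reads. The reads summed to 25073292 to 31332003 per library. The same table gave the authors' group means, a deposited log2 fold change equal to the difference of these means, a deposited p-value and a deposited FDR, which equalled a Benjamini-Hochberg adjustment over all genes of the table. No column belonged to another sample. Gene coordinates, transcript lengths and GC content came from GENCODE M21 on GRCm38, by gene identifier, for 24513 of the 24559 genes. This annotation was used for description and the length checks and may differ from the authors' own.

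The groups were L-4F and ABCT buffer, 3 libraries each, taken from the titles. The comparison, the gene lists, the genes to be named and the other settings listed below were fixed before the data were examined. The plan assumed counts or FPKM, and the table held log2 values, so the test for log-scale values was used. The filter on low values given next differs from the filters that the plan named for either case. Genes with a normalized count of at least 10 in at least 3 libraries (14922 genes) were tested on the deposited log2 values with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with a mean-dependent (trended) and robust empirical Bayes spread, group as the only term, and Benjamini-Hochberg adjustment over all genes tested. All adjusted p-values for genes are from limma and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates the change of genes with few reads. Intervals are 95% intervals from the moderated fit.

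The 42 gene lists, each with at least 4 tested members, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated per list. Fry, which tests whether a list's genes move on balance in 1 direction, was run beside it. A listed symbol absent from the table was looked up by its GENCODE M21 name, and 12 symbols, 9 of them newer names of ATP synthase genes listed under their older names as well, found no match. List counts are given over all genes and adjusted over the list alone.

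The rule for named genes took the 12 higher and 12 lower called genes with the largest absolute log2 fold change among those whose groups did not overlap and whose mean was at least 10 CPM, without predicted genes, Riken clones, pseudogenes and antigen receptor segments. It also took up to 4 members of each list with the smallest adjusted p, and 27 genes fixed in advance whatever their result. The text leaves out some of the list members, and some genes fixed in advance are not reported.

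The other settings fixed in advance were median centring, quantile normalization, no filter, a filter at 10 CPM in 3 libraries, limma without the trended robust spread, limma-voom on the recovered reads, limma with library quality weights, a pseudocount of 0.1 in place of 1, the replicate number as a block, a fold threshold of 1 on the log2 scale, and each library left out in turn. After the data were seen, removal of a smooth trend (robust loess, span 0.3) in transcript length, exon length or GC content from each library, and scaling by total reads, were added. The main test was made for log2 values because the table holds these, and limma-voom was the only test run on the recovered reads.

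Libraries of a group were compared before they were averaged. For pairs within a group the median chi-square over genes was 2.19 to 2.72 times that of counting noise, and between groups 7.72 to 8.85 times, so no library was a copy of another. The procedure was tested on simulated reads drawn from the real means and library sizes for the L-4F against buffer comparison. Of 14922 genes 200 were changed. Of those changed by 0.25 on the log2 scale 23.5% were recovered, 65.2% at 0.5 and 74.2% at 1, with 6 false calls. With a simulated length trend there were 694 false calls before and 1 after removal of the trend. The simulated trend was linear in log2 length and the same at every expression level. It does not show how fully the trend in the data was removed. In a simulation without a length trend a list of 32 genes was raised by 0.4. It passed camera with the preset correlation, camera with an estimated correlation (adjusted p = 0.00334) and fry. Of 42 unchanged lists 0, 0 and 2 were called. Genes were drawn independently of each other, so this does not show how the list tests behave where genes of a list vary together. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.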

Results

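RNA sequencing measured gene expression in CD8+ T cells from the spleens of C57BL/6 wild-type mice, which the labels describe as a primary culture. CD8+ T cells are the lymphocytes that kill infected or malignant cells. There were 3 libraries from cells treated with L-4F, a peptide that mimics apolipoprotein A1, the main protein of high-density lipoprotein, and 3 libraries from cells given ABCT buffer. The deposited values corresponded to 25073292 to 31332003 reads per library over 24559 genes, and the 10 most abundant genes took 5.05% to 5.52% of them. At this depth a count of 0 allowed up to 0.0957 to 0.120 CPM, counting error only. The first principal component held 36.9% of the variance and separated the groups. The labels do not say whether the 3 libraries of a group came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

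The comparison asks how apolipoprotein A1 affects immune functions of CD8+ T cells, and the series title names HIF-1α and glycolysis. L-4F was accompanied by small shifts in many genes. Of 14922 genes tested, 5694 (38.2%) changed, 2747 higher and 2947 lower with L-4F (limma, adjusted p under 0.05), with a median change of 1.20-fold. Genes were ranked by fold change among called genes with a mean of at least 10 CPM and no overlap between the groups, by a rule fixed in advance. In this ranking Kcna3, a voltage-gated potassium channel of T cells, fell most, from a mean of 1072 to 424 normalized reads (n = 3 per group; log2 fold change -1.35, SE 0.086). S100a4, which encodes a calcium-binding protein, rose most in it, from 321 ± 16.4 to 549 ± 51.0 normalized reads (log2 fold change 0.77, SE 0.085).

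The next genes that rose in this ranking were S100a6 (0.67), Hcst (0.63), S100a13 (0.62), Ifi27l2a (0.62), AA467197 (0.61), Ifitm1 (0.60), Tmem256 (0.59) and Rpl22l1 (0.57), all as log2 fold changes. Hcst encodes the adaptor DAP10 of the NKG2D receptor, and Ifi27l2a and Ifitm1 are interferon-inducible. The ranking also held Maskbp3 (0.64), which overlaps a neighbouring gene, Gstp3 (0.62), which has close paralogs, and mt-Ts1 (0.55), a mitochondrial transfer RNA, and these values are uncertain because reads may be shared or the RNA is very short. After Kcna3 the genes that fell in this ranking were Atp7a, a copper transporter (-1.07), Lcor, a nuclear receptor corepressor (-1.02), Klhl11 (-0.95), Prrg4 (-0.94), Lad1 (-0.90), Hipk2, a nuclear kinase (-0.90), Gprin3 (-0.86), Kmt2a, a histone H3 lysine methyltransferase (-0.86), Spen, a transcriptional corepressor (-0.85), Zfp169 (-0.84) and Pdpr (-0.83). For these 24 genes the 3 L-4F libraries lay entirely above or below the 3 buffer libraries; 47.6% of all tested genes did so, against 10% by chance. With an absolute log2 fold change of at least 1 as a further requirement, 182 genes passed, 42 higher and 140 lower. With median centring of the libraries, 37.3% of the called genes were higher (2161 higher, 3630 lower), against 48.2% in the deposited scaling. In GRCm38 coordinates of GENCODE M21, Kcna3 (ENSMUSG00000047959) lies on chromosome 3 from 107036169 to 107038070, and S100a4 (ENSMUSG00000001020) on chromosome 3 from 90603771 to 90606045. The authors' deposited table listed 5219 genes at an FDR under 0.05, 2507 higher and 2712 lower, of which 5136 were also called here, none in the opposite direction.

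**Figure D1:**
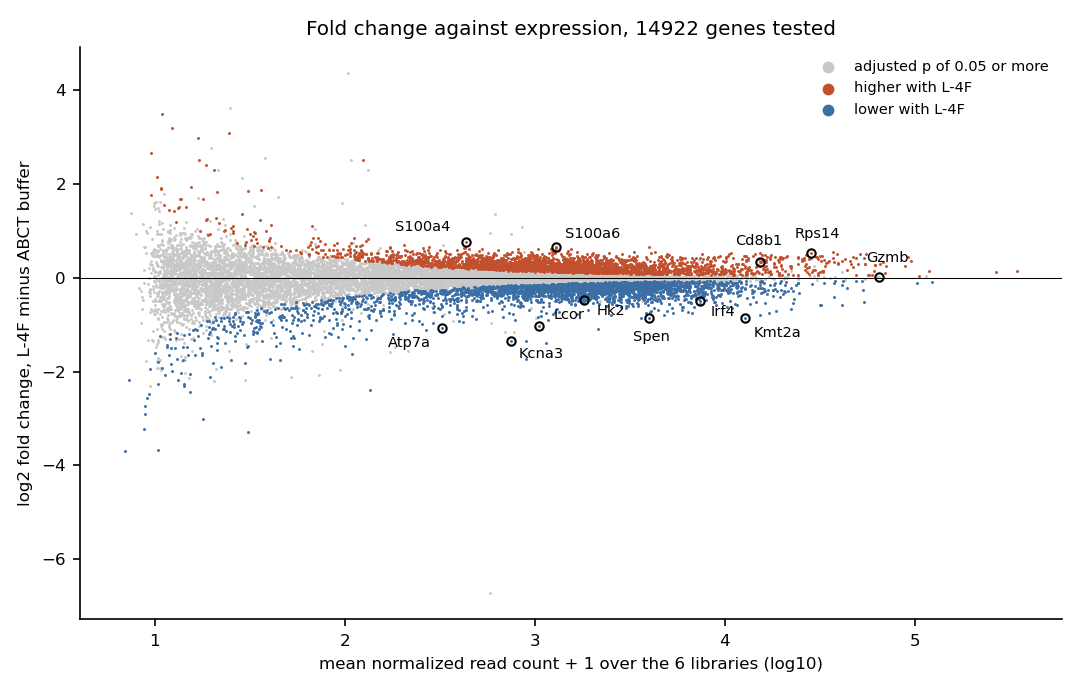
Log2 fold change, L-4F minus ABCT buffer, against the mean normalized read count plus 1 (log10 axis), 1 point per tested gene, with 12 genes circled. Red and blue points are the 2747 higher and 2947 lower genes, most of them within 1 log2 unit of 0, and grey points did not pass the threshold.

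Fold changes were related to transcript length. The rank correlation of the log2 fold change with the length of the gene's longest transcript was -0.45 across 14910 genes, which are not independent replicates. In the 10% of genes with the shortest transcripts (up to 819 nt) the median log2 fold change was 0.20, with 26.3% of genes higher and 4.96% lower. In the 10% with the longest transcripts (6327 nt or more) it was -0.28, with 2.15% higher and 63.7% lower. Slopes on log2 length were taken for each library's deviations from the gene's mean over the 6 libraries. All 3 buffer libraries had slopes between 0.0387 and 0.0428 and all 3 L-4F libraries between -0.0430 and -0.0393 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The opposite signs follow from this centring, and only the difference between the groups is measured. With a smooth length trend removed from each library, a step chosen after seeing the data, 3954 genes were called, 2059 higher and 1895 lower, and 3103 of them were also called without it, 3015 in the same direction. Among the named genes, Kcna3 (-1.46), S100a4 (0.55) and S100a6 (0.45) kept their calls, while Kmt2a (longest transcript 16470 nt) and Spen moved to -0.40 and -0.47. Of 172 called genes followed by name, 89 had a change more than 1.5 times smaller, or of the other sign, with the length trend removed. Because of this relation the median transcript length is given below beside each gene group that passed its test.

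**Figure D2:**
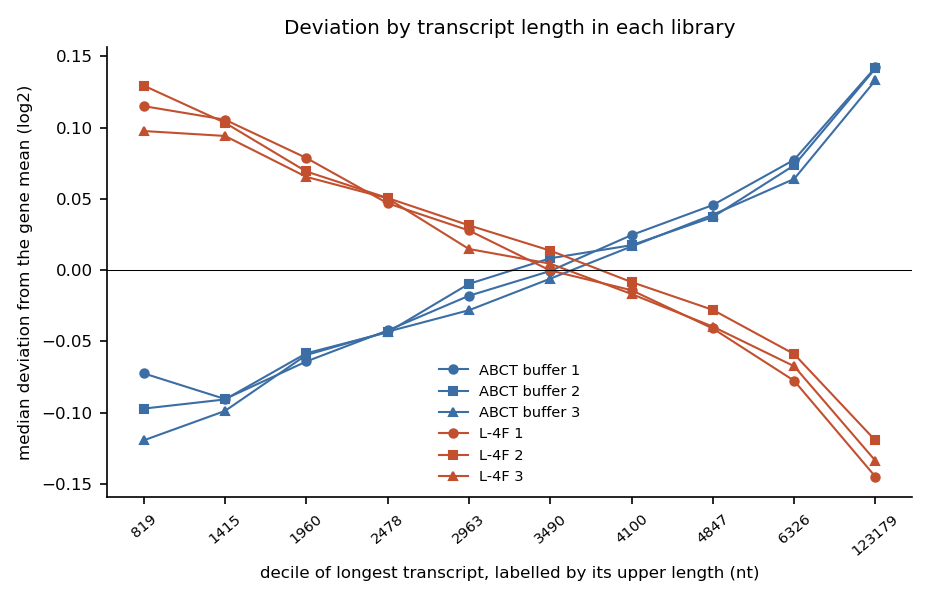
Median deviation of the log2 value from the gene's mean over the 6 libraries, for 10 equal groups of the tested genes ordered by the length of the longest transcript (nt, x axis), 1 line per library. The buffer libraries run from below 0 in short transcripts to above 0 in long ones and the L-4F libraries the other way.

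Genes of the HIF-1 and glycolysis lists moved in both directions. Hif1a, the oxygen-regulated subunit of HIF-1, fell from 8485 ± 118 to 7481 ± 111 normalized reads (SD, n = 3; log2 fold change -0.18, SE 0.025, adjusted p = 4.9e-06), and its change was -0.09 with the length trend removed. Hk2, which phosphorylates glucose at the first step of glycolysis, fell from 2118 ± 61.4 to 1518 ± 73.3 normalized reads (log2 fold change -0.48, SE 0.045), and the glucose transporter gene Slc2a1 fell with a log2 fold change of -0.19 (SE 0.048). Pgk1 (0.18), Ldha, lactate dehydrogenase A (0.14), and the enolase gene Eno1 (0.12) rose, by at most 1.14-fold. Of the 22 measured members of the glycolysis list, which counts Aldoa under 2 gene identifiers, 7 rose and 6 fell, and 7 and 7 did so adjusted over the list alone. The median was 0.02 and the glycolysis list did not pass camera (adjusted p = 0.786). Ldha and Eno1 were not called with the length trend removed (log2 fold changes 0.02 and 0.02, adjusted p = 0.452 and 0.421), and their values were -0.02 and -0.03 under quantile normalization. Pgk1 was at 0.06 and Hk2 at -0.34 without the length trend.

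Of 20 tested HIF-1 target genes outside glycolysis, 5 rose and 4 fell, 5 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.753). Higd1a (0.29), Bnip3l (0.18) and Bnip3 (0.37), which encode mitochondrial proteins, rose, and Kdm3a (-0.16), a histone demethylase, fell. The calls for Bnip3 and Kdm3a ended with the length trend removed (adjusted p = 0.0897 and 0.172). Vegfa fell with a log2 fold change of -0.22 (adjusted p = 0.0217), but not without buffer library 1 (adjusted p = 0.121), L-4F library 1 (0.0876) or L-4F library 2 (0.104), without the low-value filter (0.0596) or by limma without the trended robust spread (0.155). Arnt (-0.08, adjusted p = 0.157), Vhl (0.11, adjusted p = 0.364) and Pdk1 (0.02, adjusted p = 0.678) did not pass. Arnt did with median centring (-0.12, adjusted p = 0.035), and Pdk1 with the length trend removed (0.14, adjusted p = 0.00453). Hif1a (ENSMUSG00000021109) lies on chromosome 12 from 73901375 to 73947530, and Hk2 (ENSMUSG00000000628) on chromosome 6 from 82725025 to 82774454.

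**Figure D3:**
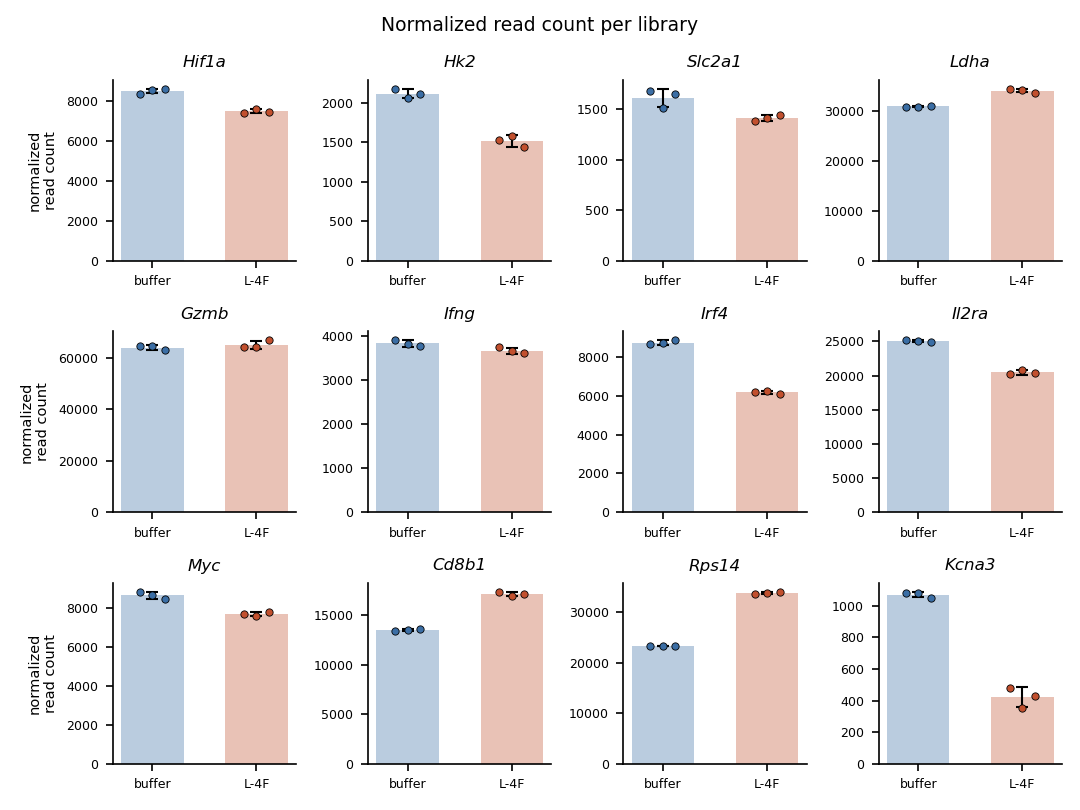
Normalized read count of 12 genes in each library (points), with the group mean (bars) and SD (error bars, n = 3). Hif1a, Hk2, Slc2a1, Irf4, Il2ra, Myc and Kcna3 are lower with L-4F, Cd8b1, Rps14 and Ldha higher, and Gzmb and Ifng did not pass the test.

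Genes of T cell activation and costimulation fell with L-4F. Of 21 list members 15 fell and 1 rose (the same counts adjusted over the list alone), with a median log2 fold change of -0.20 (camera adjusted p = 1.24e-05; adjusted p = 0.175 with an estimated correlation) and a median transcript length of 3940 nt. Irf4, a transcription factor induced by antigen receptor signalling, fell from 8719 ± 115 to 6166 ± 62.0 normalized reads (SD, n = 3; log2 fold change -0.50, SE 0.025). Il2ra, the interleukin-2 receptor alpha chain (-0.29), Nr4a3 (-0.40) and Nfatc1 (-0.30), both activation-induced transcription factors, and Myc (-0.17) also fell. Without the length trend Irf4 was at -0.40, Il2ra at -0.22, Nr4a3 at -0.24, Nfatc1 at -0.20 and Myc at -0.24. NF-kB targets went the same way, with 7 of 17 lower and 1 higher, or 8 and 1 adjusted over the list alone, among them Nfkb2 (-0.36), Rel (-0.37), Nfkb1 (-0.23) and Tnfaip3 (-0.30). The NF-kB list (median transcript 2973 nt) passed at an adjusted p of 0.0238, but not with a stricter filter on low values (adjusted p = 0.0563) or without the trended robust spread (adjusted p = 0.0613), and had an adjusted p = 0.239 with an estimated correlation. Nfkb1 was not called with a trend in summed exon length removed (-0.01, adjusted p = 0.866), and without the transcript length trend Rel was at -0.14 and Tnfaip3 at -0.12.

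Cytotoxic effector genes were on balance higher, but the main effectors were not. Of 16 tested members 9 rose and 1 fell, 9 and 2 adjusted over the list alone, with a median of 0.22 and a median transcript length of 1370 nt. Gzma (0.52), Nkg7 (0.35), Cst7 (0.29) and Srgn (0.27), which encode granule proteins, rose. Gzmb, granzyme B, was at 63993 ± 983 and 65046 ± 1598 normalized reads (SD, n = 3; log2 fold change 0.02, 95% interval -0.01 to 0.06, adjusted p = 0.333), and Prf1, perforin, had a log2 fold change of -0.06 (95% interval -0.18 to 0.06), and passed only with a trend in summed exon length removed (-0.16, adjusted p = 0.0417). The list passed camera (adjusted p = 0.0028; adjusted p = 0.175 with an estimated correlation) but not with the length trend removed (median 0.12, adjusted p = 0.204), where Gzmb was at -0.13 (adjusted p = 1.07e-05). Gzmb was also at -0.14 under quantile normalization. Without the length trend Gzma was at 0.32, Nkg7 at 0.15 and Srgn at 0.14, and Cst7 was not called (0.09, adjusted p = 0.0607). Natural killer cells express these granule genes as well, and 4 of 10 tested natural killer cell markers rose (5 adjusted over the list alone, median 0.27, list adjusted p = 0.0723). With the length trend removed 2 of these markers were higher (median 0.18, camera adjusted p = 0.208). The rise of the granule genes therefore cannot be assigned to CD8+ T cells.

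Among 18 tested cytokine and chemokine genes 3 rose, Ltb (0.30), Ccl5 (0.37) and Lta (0.12), and 1 fell, Il3 (-2.26, from 20.5 to 6.11 normalized reads). Adjusted over the list alone 3 rose and none fell, and leaving out any library but L-4F library 1 ended the call for Il3 (adjusted p from 0.0541 to 0.122), and without L-4F library 3 its value was -1.19 (SE 0.463). Ifng (-0.06, 95% interval -0.13 to 0.00, adjusted p = 0.13), Tnf (-0.02, adjusted p = 0.733) and Il2 (-0.20, adjusted p = 0.405) did not pass, and the list did not pass (median -0.03, mean -0.10, although camera ranked it upward, adjusted p = 0.855). With the length trend removed, Ifng (-0.24, adjusted p = 3.92e-06) and Tnf (-0.16, adjusted p = 0.00253) fell, Ltb was at 0.14, Ccl5 at 0.15 and Lta at -0.04, and the cytokine list was lower (median -0.18, adjusted p = 0.0108; adjusted p = 0.255 with an estimated correlation). Ifng also passed with median centring (-0.10, adjusted p = 0.0125) and total-read scaling (-0.08, adjusted p = 0.0462).

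Of 16 tested genes of inhibitory receptors and exhaustion 4 fell and none rose, 3 and 0 adjusted over the list alone (median -0.13, adjusted p = 0.219), among them Nr4a2 (-0.42), Cd200 (-0.25) and Nt5e (-0.17), the last not with a trend in summed exon length removed (-0.02, adjusted p = 0.641). Pdcd1, which encodes PD-1, was at -0.14 (adjusted p = 0.0855), at -0.17 without L-4F library 1 (adjusted p = 0.0487) and at -0.25 with the length trend removed (adjusted p = 0.00391), where the list passed (adjusted p = 0.0255; adjusted p = 0.192 with an estimated correlation). Pdcd1 also passed with median centring (adjusted p = 0.0271), removal of an exon length trend (0.00118) and removal of a GC trend (0.0399). Naive and memory T cell genes went both ways, 5 higher and 6 lower of 19, the same adjusted over the list alone (adjusted p = 0.938). Igfbp4 (0.52) and Klf2 (0.34) rose while Bach2 (-0.49) fell, and Tcf7 (-0.04, adjusted p = 0.161) did not pass. Without the length trend Igfbp4 was at 0.56, Klf2 at 0.22 and Bach2 at -0.20. Tcf7 was called lower with median centring (-0.08, adjusted p = 0.00772), removal of the transcript length (-0.10, 0.0012), exon length (-0.13, 8.08e-05) or GC trend (-0.06, 0.0352), and total-read scaling (-0.06, 0.0447). With the length trend removed the naive and memory list was higher (median 0.11, adjusted p = 0.0435; adjusted p = 0.216 with an estimated correlation), but did not pass with the exon length trend removed (adjusted p = 0.081). Of 17 effector differentiation genes 4 rose and 4 fell, 4 and 5 adjusted over the list alone (adjusted p = 0.769), with Il12rb2 (-0.59), Zeb2 (-0.69) and Runx3 (-0.23) lower and Klrd1 (0.36) higher. Without the length trend Il12rb2 was at -0.61, Zeb2 at -0.39, Runx3 at -0.19 and Klrd1 at 0.15. Tbx21 (-0.08, adjusted p = 0.12) did not pass, but was called lower without buffer library 2 (adjusted p = 0.0462) or L-4F library 2 (0.0327), with median centring (-0.12, 0.0191) and with the transcript length (-0.15, 0.0117) or exon length trend removed (-0.19, 0.00159).

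In the T cell receptor and proximal signalling list 8 of 19 genes rose and 7 fell, 8 and 8 adjusted over the list alone (adjusted p = 0.753). Cd8b1, the beta chain of the CD8 coreceptor, rose from 13491 ± 107 to 17134 ± 213 normalized reads (SD, n = 3; log2 fold change 0.34, SE 0.021), and Cd3g rose (0.41), while Ptprc, CD45 (-0.26), fell. Ptprc was at 0.06 with a trend in summed exon length removed, but stayed lower with the transcript length trend removed (-0.11, limma, adjusted p = 8.98e-06). In the latter setting Cd8b1 was at 0.19 and Cd3g at 0.36. Cd8a rose by 0.12 in log2 fold change (adjusted p = 3.24e-05), but was at -0.05 under quantile normalization and not called by limma without the trended robust spread (adjusted p = 0.0502). Cd3e (0.05, adjusted p = 0.184) did not pass, but did without L-4F library 2 (0.09, adjusted p = 0.016) and under quantile normalization (0.09, adjusted p = 0.0337).

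Ribosomal protein genes and most nuclear genes of the respiratory chain rose. All 32 ribosomal protein genes of the list rose, adjusted over all genes and adjusted over the list alone, with a median log2 fold change of 0.40 and a median transcript length of 1124 nt. Rps14 rose from 23354 ± 54.0 to 33843 ± 263 normalized reads (SD, n = 3; log2 fold change 0.54, SE 0.018), followed by Rps4x (0.43), Rps6 (0.43) and Rpl19 (0.41). Of 46 nuclear genes of oxidative phosphorylation 42 rose and none fell (43 and 0 adjusted over the list alone), with a median of 0.26 and a median transcript length of 1298 nt, among them Uqcrh (0.46), Atp5h (0.40), Atp5c1 (0.37) and Atp5pb (0.30). Camera gave adjusted p = 4.28e-33 for ribosomal proteins (adjusted p = 0.175 with an estimated correlation) and 4.58e-17 for oxidative phosphorylation (adjusted p = 0.136 with an estimated correlation). With the length trend removed the medians were 0.22 (adjusted p = 9.58e-30) and 0.11 (adjusted p = 4.11e-06), each with an adjusted p = 0.171 with an estimated correlation, and 30 of 32 and 18 of 46 genes were called higher, with 0 and 1 lower.

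Transcripts encoded by the mitochondrial genome diverged, with 7 of 13 higher and 4 lower (the same adjusted over the list alone; list adjusted p = 0.426). The genes mt-Co3 (0.29), mt-Co2 (0.27) and mt-Co1 (0.13) of complex IV rose. Those of complex I went both ways, with mt-Nd3 (0.34) and mt-Nd1 (0.10) higher and mt-Nd4l (-0.54), mt-Nd5 (-0.52, from 63868 ± 1249 to 44626 ± 445 normalized reads) and mt-Nd2 (-0.07) lower. Under quantile normalization mt-Nd1 was at -0.08 (adjusted p = 0.000144), and limma without the trended robust spread called neither mt-Nd1 (adjusted p = 0.0628) nor mt-Nd2 (0.152). With the GC trend removed mt-Nd2 was at 0.00 (adjusted p = 0.996). Without the length trend mt-Co1 was at -0.02 (adjusted p = 0.252) and mt-Nd1 at -0.10 (adjusted p = 4.82e-05). In that setting mt-Co3 was at 0.08, mt-Co2 at 0.05, mt-Nd3 at 0.12, mt-Nd2 at -0.26, mt-Nd5 at -0.64 and mt-Nd4l at -0.75. There 3 of the 13 were higher and 9 lower (median -0.15, adjusted p = 1.11e-06; adjusted p = 0.177 with an estimated correlation). In the tricarboxylic acid cycle 8 of 21 genes rose and 1 fell, the same adjusted over the list alone (median 0.06, median transcript 2636 nt, adjusted p = 0.0252; adjusted p = 0.224 with an estimated correlation), with Sdhd (0.26), Sdhb (0.27), Sucla2 (0.21) and Suclg1 (0.18) among them. This call ended with median centring (adjusted p = 0.135), total-read scaling (0.0565), the stricter filter (0.0563) and removal of the length trend (0.646), which also ended the calls for Sdhd (0.0952) and Sdhb (0.0739). Of 18 fatty acid oxidation genes 13 rose and 1 fell, the same adjusted over the list alone (median 0.19, median transcript 2562 nt, adjusted p = 0.00338; adjusted p = 0.239 with an estimated correlation). Etfb (0.35), Acaa2 (0.30) and Hadhb (0.27) rose, and Cpt1a, which controls entry of fatty acids into mitochondria, fell (-0.24). The list median was 0.11 with the length trend removed, and Acaa2 was not called with the exon length trend removed (adjusted p = 0.0551).

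Amino acid transport and mTORC1 genes fell, 9 of 14 lower and 2 higher, the same adjusted over the list alone (median -0.20, median transcript 4788 nt, adjusted p = 0.00338; adjusted p = 0.175 with an estimated correlation). Mtor (-0.52), a kinase that couples nutrients to growth, and the transporter genes Slc7a1 (-0.42), Slc38a2 (-0.29) and Slc38a1 (-0.28) fell. With the length trend removed the median was -0.10, Mtor was at -0.24, Slc7a1 at -0.19 and Slc38a2 at -0.11, while Slc38a1 was no longer called (-0.05, adjusted p = 0.136) and was at 0.03 with a trend in summed exon length removed. Fatty acid synthesis genes went both ways, 2 of 14 higher and 4 lower, the same adjusted over the list alone (adjusted p = 0.393), with Acaca (-0.41), Fasn (-0.35), Acly (-0.26) and Acsl4 (-0.24) lower. Without the length trend Fasn (-0.02, adjusted p = 0.578) and Acaca (-0.10, adjusted p = 0.0625), whose longest transcripts are 10050 and 9513 nt, were not called.

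Apolipoprotein A1 accepts cholesterol from cells through ABCA1, so genes of cholesterol handling were also listed in advance. In the list of cholesterol efflux and LXR targets 2 of 12 genes rose, Smpdl3a (0.31) and Abcg1 (0.22), and Scarb1, an HDL receptor, fell (-0.26), the same adjusted over the list alone (adjusted p = 0.948). The call for Abcg1 ended without buffer library 1, buffer library 2, L-4F library 1 or L-4F library 2 (adjusted p = 0.166, 0.056, 0.0785 and 0.113), and under 4 other alternatives. Scarb1 was not called by limma without the trended robust spread (adjusted p = 0.104) or with the exon length trend removed (-0.12, adjusted p = 0.229). Abca1 had a log2 fold change of -0.48 at 103 and 74.2 normalized reads (adjusted p = 0.0619). It passed without buffer library 2 (adjusted p = 0.0255) or L-4F library 3 (adjusted p = 0.00826) and with median centring (adjusted p = 0.043). With the length trend removed Abca1, whose longest transcript is 10262 nt, was at -0.15 (limma, adjusted p = 0.639). Abcg1 was then called higher (0.38, adjusted p = 0.00084), with Smpdl3a at 0.20 and Scarb1 at -0.28. Of 24 genes of cholesterol synthesis and uptake 8 rose and 2 fell, 8 and 5 adjusted over the list alone (adjusted p = 0.515), with Ebp (0.33), Acat2 (0.25), Fdft1 (0.21) and Cyp51 (0.17) higher.

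Oxidative stress, interferon and replication genes were on balance higher. Of 19 NRF2 genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone, with a median of 0.19 and a median transcript length of 2294 nt (adjusted p = 0.00038; adjusted p = 0.175 with an estimated correlation). Gpx4 (0.45), Prdx1 (0.43), Sod1 (0.34) and Ftl1 (0.29) rose, and the median was 0.09 without the length trend. Of 38 interferon-stimulated genes 17 rose and 4 fell, 18 and 4 adjusted over the list alone (median 0.12, median transcript 3182 nt, adjusted p = 0.00338; adjusted p = 0.245 with an estimated correlation), with Psmb8 (0.30), Gbp2 (0.26) and Igtp (0.25) higher and Gbp7 (-0.35) lower. Of 28 S phase genes 11 rose and 2 fell, 12 and 4 adjusted over the list alone (median 0.09, median transcript 3254 nt, adjusted p = 0.0202; adjusted p = 0.202 with an estimated correlation), with Pcna (0.29), Tyms (0.23), Slbp (0.22) and Mcm6 (0.14) higher. Of 19 genes of ER chaperones and the unfolded protein response 9 rose and 2 fell, the same adjusted over the list alone (median 0.08, median transcript 2461 nt, adjusted p = 0.0127; adjusted p = 0.283 with an estimated correlation), with Manf (0.30), Xbp1 (0.24) and Pdia3 (0.15) higher and Sel1l (-0.32) lower. The S phase call ended with median centring (adjusted p = 0.102) and the stricter filter (0.0563), and the ER call with median centring (0.067), quantile normalization (0.0755), the stricter filter (0.053) and removal of an exon length trend (0.133). Without the length trend Gpx4 was at 0.25, Prdx1 at 0.35, Sod1 at 0.38 and Ftl1 at 0.09. Psmb8 was then at 0.18, Gbp2 at 0.20, Igtp at 0.14 and Gbp7 at -0.20. Pcna was at 0.14, Tyms at 0.27, Slbp at 0.20 and Mcm6 at 0.21, and Manf at 0.22, Xbp1 at 0.15, Pdia3 at 0.11 and Sel1l at -0.13.

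**Figure D4:**
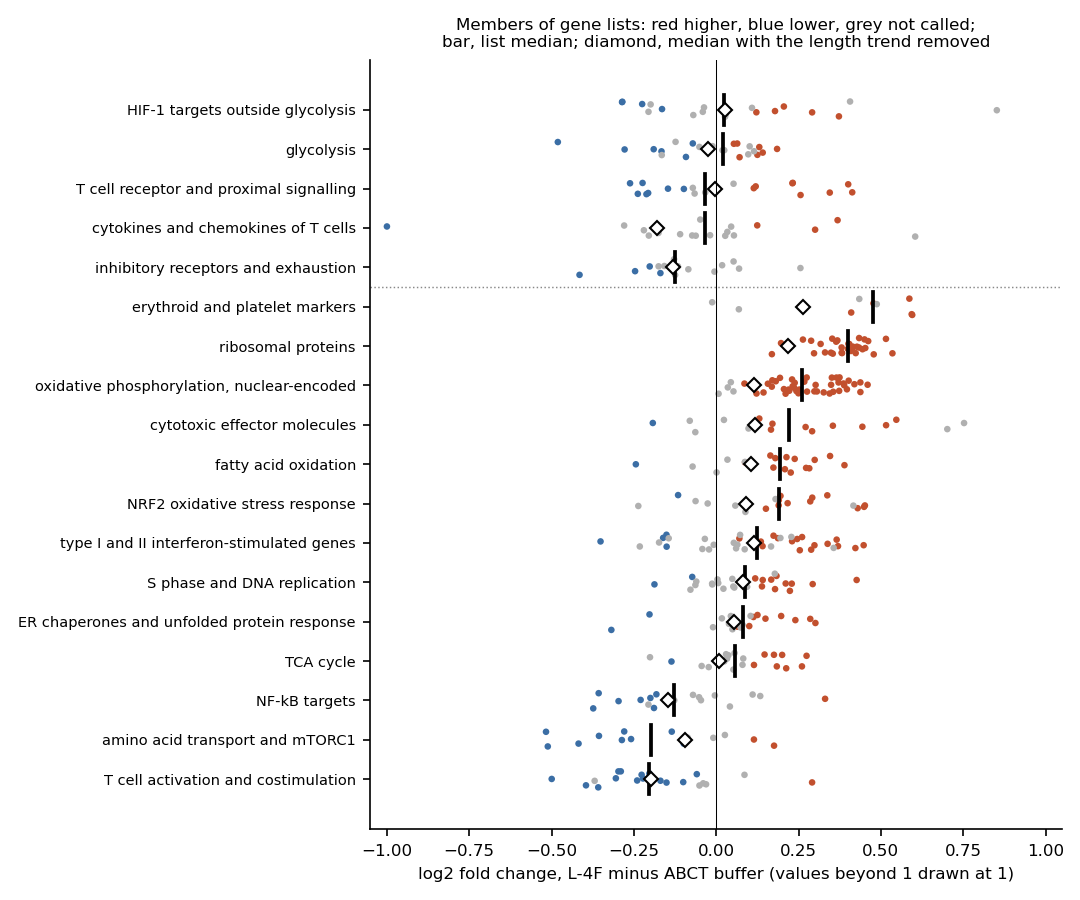
Log2 fold change of each tested member of 18 gene lists (points), the 13 lists that passed camera under the dotted line and 5 others above it, with the list median (bar) and the median after removal of the length trend (diamond). The ribosomal protein median is 0.40 and moves to 0.22, and the T cell activation median stays at -0.20.

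Markers of other cells that a spleen preparation could hold were measured as well. Of 9 tested erythroid and platelet markers 5 rose and none fell, 6 and 0 adjusted over the list alone (median 0.48, median transcript 703 nt, adjusted p = 0.0238; adjusted p = 0.224 with an estimated correlation), with Pf4 (0.48) and Ppbp (0.41) from platelets and the globin gene Hbb-bs (0.60, at 82.8 and 124 normalized reads, with a close paralog) among them. After removal of the length trend neither this list (median 0.26, adjusted p = 0.103) nor Hbb-bs (0.38, adjusted p = 0.0916) passed. Of 11 tested neutrophil markers 3 rose, Elane (0.83), S100a9 (1.10) and S100a8 (1.12), at means under 170 normalized reads, and of 10 natural killer cell markers 4 rose, among them Fcer1g (0.49). In the list alone 3 and 5 rose (adjusted p = 0.136 and 0.0723 for the lists). The natural killer list passed without buffer library 2 (adjusted p = 0.0453) or L-4F library 2 (0.0386), without the low-value filter (0.0135) and by limma without the trended robust spread (0.0288). It did not pass with the length trend removed (median 0.18, camera adjusted p = 0.208). Of 8 gamma-delta and invariant T cell markers 4 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.132, and 0.0491 without the low-value filter), with Trgc4 (0.50) and Trgc1 (0.50) higher, and these have close paralogs. Monocyte and macrophage markers went both ways, 3 of 17 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.753), with Ly6c2, which CD8+ T cells also express, higher (0.47), Marco lower (-2.11, from 30.7 to 6.29 normalized reads) and Mpeg1 lower (-0.32). Of 10 B cell markers Cd79b rose (0.52) and no other passed, the same count adjusted over the list alone (adjusted p = 0.752). Dendritic cell markers had 2 of 10 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.87). Markers of CD4 and regulatory T cells had none higher and 3 of 9 lower, 1 and 4 adjusted over the list alone (adjusted p = 0.38). None of the 4 tested stromal and endothelial markers passed, nor did any adjusted over the list alone (limma; list adjusted p = 0.794).

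In all, 13 of 42 gene lists passed camera with a preset correlation between genes of 0.01, and none of the 13 held with an estimated correlation, whose lowest adjusted p was 0.136. The replicates within a group gave the 5694 calls a tight basis in spread, but 3 libraries of unknown independence per group limit what the calls say beyond these samples.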

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

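The alternatives on length, GC content and total reads were chosen after seeing the data, and the others before the data were examined. Leaving out 1 library gave 4816 to 5362 changed genes, 2357 to 2556 higher and 2459 to 2823 lower, and 13 to 14 gene lists, against 5694, 2747, 2947 and 13. An added fold threshold left 182 genes, 42 higher and 140 lower, by its construction. With the transcript length trend removed 1895 genes were lower. Of the 13 lists, 0 passed with an estimated correlation and 8 with the stricter filter, which tests fewer genes, and 27 lists passed fry, which asks another question; the cause was not tested further. The other settings with all 6 libraries called 3954 genes (transcript length trend removed) to 5841 (GC trend removed). Of 172 called genes followed by name, 164 kept call and direction with each library left out in turn and 149 with the transcript length trend removed; of the 13 lists 13 and 10 did. Under the settings fixed in advance with all 6 libraries, leaving aside the fold threshold, the estimated correlation and fry, 157 genes and 9 lists did wherever they were tested, and the erythroid and platelet list was not tested with the stricter filter.

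Some values changed sign. Under quantile normalization Ldha was at -0.0230, Eno1 at -0.0300, Gzmb at -0.14, Cd8a at -0.0463, mt-Nd1 at -0.0837 and mt-Co1 at -1.84e-15, a difference of 0 within rounding error. With the transcript length trend removed the list median was -0.15 for mitochondrially encoded transcripts, and Lta was at -0.0365, Bax at -0.000168, Mki67 at 0.0404, mt-Co1 at -0.0169, mt-Nd1 at -0.10 and Gzmb at -0.13. The cytokine and the naive and memory lists changed only their camera direction there. Their medians kept their sign, from -0.03 to -0.18 for cytokines and from 0.01 to 0.11 for naive and memory genes. With the exon length trend removed the mitochondrial list was at -0.15, Slc38a1 at 0.0259, Ptprc at 0.0567, Lta at -0.0497, mt-Co1 at -0.0395, mt-Nd1 at -0.0873 and Gzmb at -0.15. The cytokine list, with a median of -0.18, again changed only its camera direction. With the GC trend removed mt-Nd2 was at 0.000224. The cause was not tested beyond the length relation itself.

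With the replicate number as a block 5521 genes were called, 2655 higher and 2866 lower, and 13 lists. The numbers share no stated origin, and the deviations of same-numbered libraries correlated at 0.051, 0.011 and 0.109 across genes, so they are not taken to pair the samples, although buffer libraries 1 and 3 correlated best with the L-4F library of their own number and buffer library 2 with L-4F library 1 (0.023). The planned test of FPKM beside counts was not run, since the table holds only log2 values, and of the count tests planned only limma-voom was run. At this depth and n, with 200 of 14922 genes changed, simulated changes of 0.25 on the log2 scale were recovered for 23.5% of genes. In the data 38.2% of genes were called, which makes the adjusted threshold less strict, so this share is not the recovery in the data.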

Other observations

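The test on immunoglobulin segments was chosen after its values were seen, and the length and GC corrections were added after the data were seen. Most of the further lists fixed in advance held genes moving in both directions. In the ATF4 integrated stress response 10 of 22 genes rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.38), with Trib3 (0.31), Atf4 (0.19) and Phgdh (0.16) higher and Aldh18a1 (-0.20) lower; Phgdh was not called with the length trend removed (0.04, adjusted p = 0.173). Of 19 ribosome biogenesis genes 3 rose and 7 fell, 6 and 8 adjusted over the list alone (adjusted p = 0.426), with Utp20 (-0.50), Polr1a (-0.39) and Ddx21 (-0.21) lower and Fbl (0.17) higher. With the length trend removed Utp20 was at -0.21, Polr1a at -0.09, Ddx21 at -0.11 and Fbl at 0.11. Of 17 homing genes 5 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.753), with the integrin genes Itga4 (-0.57) and Itgal (-0.24) and the chemokine receptor Ccr9 (-0.52) lower and Itgb7 (0.28) higher. Without the length trend Itga4 was at -0.25, Itgal at -0.12, Ccr9 at -0.40 and Itgb7 at 0.23. Of 28 mitotic genes 10 rose and 6 fell, 11 and 6 adjusted over the list alone (adjusted p = 0.549), with Birc5 (0.31), Cdk1 (0.28) and Nusap1 (0.21) higher and Mki67 lower (-0.29), the last at 0.04 with the length trend removed.

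Of 19 p53 and apoptosis genes 3 rose and 8 fell, the same adjusted over the list alone (adjusted p = 0.221), with Bax (0.19) higher and Tnfrsf10b (-0.27) and Zmat3 (-0.26) lower. With the length trend removed the calls for Bax (-0.000168, adjusted p = 0.998) and Zmat3 (-0.01, adjusted p = 0.83) ended. Of 11 pentose phosphate genes 3 rose and none fell, the same adjusted over the list alone (adjusted p = 0.105, but 0.0375 under quantile normalization and 0.0241 without the low-value filter), among them Pgls (0.31) and Taldo1 (0.29). Of 14 STAT5 and interleukin-2 targets 4 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.753), with Osm (0.35) and Ccnd3 (0.22) higher and Il2ra lower (-0.29). Heat shock genes had 3 of 13 higher and 3 lower, 5 and 3 adjusted over the list alone (adjusted p = 0.753), with Hspe1 (0.30), Dnaja1 (0.22) and Hspa8 (0.15) higher. Immediate-early and dissociation genes had 3 of 15 higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.763), with Jund (0.27) higher and Atf3 (-0.37) lower; Jund was not called with the length trend removed (0.13, adjusted p = 0.0997). Of 7 tested replication-dependent histone genes 2 rose and none fell, 1 and 0 adjusted over the list alone (adjusted p = 0.549).

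The first pattern is the relation of fold change to transcript length and the lists that moved with it. Removing the length trend left the ribosomal protein median at 0.22 (SE 0.025) and the T cell activation median at -0.20 (SE 0.045). The SEs of list medians were taken over the genes of a list as if independent, and do not measure the spread between libraries. They may be too small, since the estimated correlation between ribosomal protein genes was 0.27. The trend was fitted over all genes of a library at once. The rank correlation of fold change with length was -0.23 at low, -0.60 at middle and -0.72 at high expression. Ribosomal protein genes are abundant (Rps14 at 23354 normalized reads with buffer), so some of the trend may remain in them. The test therefore cannot decide whether length bias is the whole cause of their rise. The activation median was -0.20 before and after removal, so the trend fitted over all genes did not account for it. Some activation genes are abundant too, with Il2ra at 25193, 25046 and 24931 normalized reads in the buffer libraries (longest transcript 4412 nt). Some of the trend may remain in these genes as well, so the test cannot decide whether length bias causes their fall. Oxidative phosphorylation was left at 0.11 (SE 0.020), too close to the bound of 0.1 set beforehand to be told apart from bias. Removing a GC trend left 0.38 and -0.22 for the ribosomal and activation lists, which argues against GC content. The slopes of the groups were separated by a gap of 0.0781, against a widest range within a group of 0.00408, so no single library makes the trend. Intron length given transcript length had a partial rank correlation across genes of -0.00163, against -0.37 for transcript length given intron length. This argues against reads from introns, but how reads were counted is not given. If only exons were counted, unspliced RNA need not follow intron length, and the test cannot exclude it. A difference in RNA integrity or fragment size between the groups may be the cause, since the trend held at low, middle and high expression, with a rank correlation of -0.23 where it was weakest, but it follows the groups exactly, and a biological effect of L-4F on long transcripts remains open and untested.

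The second pattern is in immunoglobulin V segments, of which 7 rose and 24 fell among 53 tested. Igkv4-55 had 3.53, 1.89 and 0 normalized reads in the buffer libraries and 21.1, 24.8 and 16.7 with L-4F, and Ighv9-2 had 27.3, 37.7 and 27.8 against 2.23, 1.99 and 5.20, both chosen after their values were seen. Between groups the spread of these segments was 2.25 times that of other genes with like read numbers, but within groups it was 0.651 times. If the 3 libraries of a group came from 1 shared pool of cells, a large spread between groups and a small one within them would follow, so such a pool may be the cause. T cell receptor V segments (5 higher and 0 lower of 125) showed no such excess between groups, at 0.484 times matched genes, and separate cultures from mice with alike segments stay open.

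The last pattern is the rise of erythroid and platelet markers. The summed reads of the 3 most abundant members, Itga2b, Pf4 and Ppbp, rose by a log2 ratio of 0.22 (SE 0.033). This lies below the list median of 0.48 and above the bound of 0.1 set beforehand. A larger share of platelets in the L-4F libraries can therefore neither be excluded nor held to be likely. No globin gene was in this sum, so it does not test a larger share of red cells. Itga2b was at -0.01 and the listed transcripts are short (median 703 nt), which leaves the length relation open as well; no other explanation was tested.

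Some genes differed many-fold between libraries of the same group, which was looked for after the results were seen. Of 11915 tested genes with a mean of at least 50 normalized reads, 34 differed at least 4-fold within a group, and limma called none of them. Qser1 had 0, 690.5 and 0 normalized reads in the L-4F libraries and 916, 909 and 979.5 in the buffer libraries, and Zbtb38 had 146, 725 and 831 with L-4F and 979.9, 973 and 1003 with buffer. None of the 34 is a member of a gene list or among the genes named by the rule, most are predicted genes, and the cause was not tested.

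Of the 10 splits of the 6 libraries into 3 and 3, the real 1 gave 5694 genes and the highest of the others 1; it gave 13 lists and the highest of the others 7. With 10 splits no share under 0.05 can be reached.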
